A study of Mus musculus with 3 samples.

How the data were processed

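RNA from CD1 mouse embryos, a pool of both sexes, was compared on 3 two-colour oligonucleotide arrays of the Compugen mouse set. Per the labels, each array carried microdissected metanephric mesenchyme of 10.5 days post coitum (dpc) in channel 1 and metanephroi of 11.5 dpc in channel 2, as amplified RNA labelled with amino allyl dyes. The dye order was red/green on arrays 1 and 2 and green/red on array 3. There was no common reference, so every array holds the whole comparison within itself. The labels do not tell whether the arrays came from separate dissections or from the same extracts, and p-values here measure only the spread between these arrays, which may be technical.

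Per the labels' descriptions, the authors read the spots with Imagene 5.5 and normalized them in R by print-tip lowess and between arrays. The descriptions also give a lowess fit of log ratio on log intensity over 20% of the data at each point, with control channel values under 10 set to 10. The deposited values are log2 ratios of the 2 channels on each array, and the lowest ratio in the table was 0.01. They were used as the authors normalized them. Which channel is the numerator is not given in the sources used here, so ratios are called positive or negative and no tissue is assigned to either side. The genome build is not given in the sources used here and no coordinates are printed. Intensities were not analysed here, so how far a spot lay above background is unknown, and the number of arrays limits the precision.

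The table had 22702 rows, of which 21918 were gene probes, 563 were blank, empty or buffer spots without a value, and 221 were other control spots. Gene probes with a value numbered 21354 on array 1, 19883 on array 2 and 21396 on array 3, and 19660 had one on all 3 arrays. Control spots stayed out of the tests. In the platform annotation 16656 gene probes had 1 gene symbol, 137 had several and 5125 had none. Updating symbols through Entrez identifiers, which matched for 15970 probes, changed 0 of them. Probes of 1 symbol were averaged per array, which gave 14047 genes with values on all 3 arrays. Of the 916 genes with more than 1 probe, 493 had probe means of opposite sign.

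Array 3 was checked for its orientation by a rule fixed before the data were examined. Its ratios correlated above 0 with both other arrays across probes, at a Pearson correlation of 0.0517 with array 1 and 0.0148 with array 2, so it was taken as already turned by the submitters. Both correlations are close to 0, and the results with array 3 turned the other way are given as an alternative.

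The mean log2 ratio of the 3 arrays was tested against 0, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05, for probes and for genes. Values after ± are SDs over the arrays. Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members, out of 30 lists fixed before the data were examined. Plots were drawn with Matplotlib 3.10.9 in Python 3.11.15.

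The rule for named genes was also fixed before the data were examined. It takes per side the 12 genes with the largest mean ratio among those past the adjusted threshold with the same sign on all arrays. The rule fills empty places with the genes of smallest unadjusted p on that side that also have the same sign on all arrays. To these it adds up to 4 members of each list by smallest unadjusted p, and a set of kidney development genes named wherever measured. As no gene passed, all 24 places of the first part were filled by unadjusted p. Other members are named below only as examples of a list's count, and were then chosen after their values were seen.

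The tests were run first on simulated data for 3 arrays, with 200 changed features among 19660 probes or 14047 genes. Other numbers of changed features were not simulated, so the adjusted calls need not hold for data with a larger share changed. At an adjusted p under 0.05, a true log2 ratio of 1 or of 2 gave 0 calls at both levels. A log2 ratio of 3 gave 93 of the changed probes with 6 false calls, and 150 of the changed genes with 6 false calls. At an unadjusted p under 0.05 the changed genes were found in 83% of cases for a log2 ratio of 1, in 92.5% for 2 and in 99.5% for 3. In the simulated list test every endothelium member was shifted by a log2 ratio of 1 in independent noise. It called the shifted list and 0 others. Smaller shifts and correlated members were not simulated.

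Alternatives fixed before the data were examined were median centring, scaling to one median absolute deviation, values on at least 2 arrays, a dye term, array 3 turned the other way, robust and unmoderated variances, array weights, limiting extreme values, a 1.5-fold minimum, other ways of joining probes, each array left out in turn, an estimated inter-gene correlation, and fry. Counts by limma's B statistic and at an unadjusted p, and an estimated inter-gene correlation together with the dye term, were added after seeing the data. With an estimated correlation, camera rests on the few degrees of freedom that the arrays leave. A call lost there need not come from correlated members.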

Results

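The kidney of the mouse begins at about 10.5 dpc as the metanephric mesenchyme, and by 11.5 dpc the ureteric bud, an epithelial outgrowth, lies inside it and the whole is called the metanephros. The design set these stages against each other on 3 arrays, which asks which transcripts differ between mesenchyme at 10.5 dpc and the metanephros at 11.5 dpc. Ratios were available for 19660 probes and 14047 genes on all 3 arrays. The labels do not settle which tissue is the numerator. A positive ratio therefore stands for more RNA in 1 of the tissues and a negative ratio for more in the other, without saying which.

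On the positive side were Wt1, a zinc finger transcription factor needed for the metanephric mesenchyme, with a mean log2 ratio of 1.75 ± 0.04 (SD, n = 3), and Crym, a thyroid hormone binding protein, at 1.91 ± 0.10. Foxd1, a transcription factor of the renal stroma, lay on the same side at 1.56 ± 0.17. On the negative side were the skeletal muscle actin gene Acta1 at -4.96 ± 0.92, the transcription factor genes Zic1 at -3.47 ± 0.28 and Irx5 at -3.35 ± 0.48, and the imprinted gene Dlk1 at -2.46 ± 0.13. Afp, the alpha-fetoprotein of yolk sac and fetal liver, had -1.68 ± 0.07. Each of these genes had the same sign on all 3 arrays, which the rule required of all but Foxd1, and none passed adjustment over all genes. By limma, 0 of 14047 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.149.

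The other genes taken on the positive side were Sel1l3 at 2.36 ± 0.17, Kantr at 2.17 ± 0.10, the splicing factor gene Rbfox1 at 2.62 ± 0.26, the matrix Gla protein gene Mgp at 2.04 ± 0.24, the adenylate kinase gene Ak5 at 1.98 ± 0.19, the iron exporter gene Slc40a1 at 1.78 ± 0.02 and the autophagy gene Atg101 at 1.80 ± 0.15. 1600027J07Rik had 2.22 ± 0.23, Rab26os had 2.02 ± 0.23 and Slc22a16 had 1.63 ± 0.08. On the negative side were also Anapc7, a subunit of the anaphase promoting complex, at -3.05 ± 0.20, Ogfr at -2.65 ± 0.39, Gpat4 at -2.25 ± 0.04, Fam162b at -2.11 ± 0.29, the calponin gene Cnn2 at -1.82 ± 0.17, the kinase gene Dapk3 at -1.70 ± 0.16 and the apolipoprotein gene Apoa1 at -1.58 ± 0.10. All 24 genes had an adjusted p of 0.149 by limma and the same sign on every array, the latter because the rule required it.

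**Figure D1:**
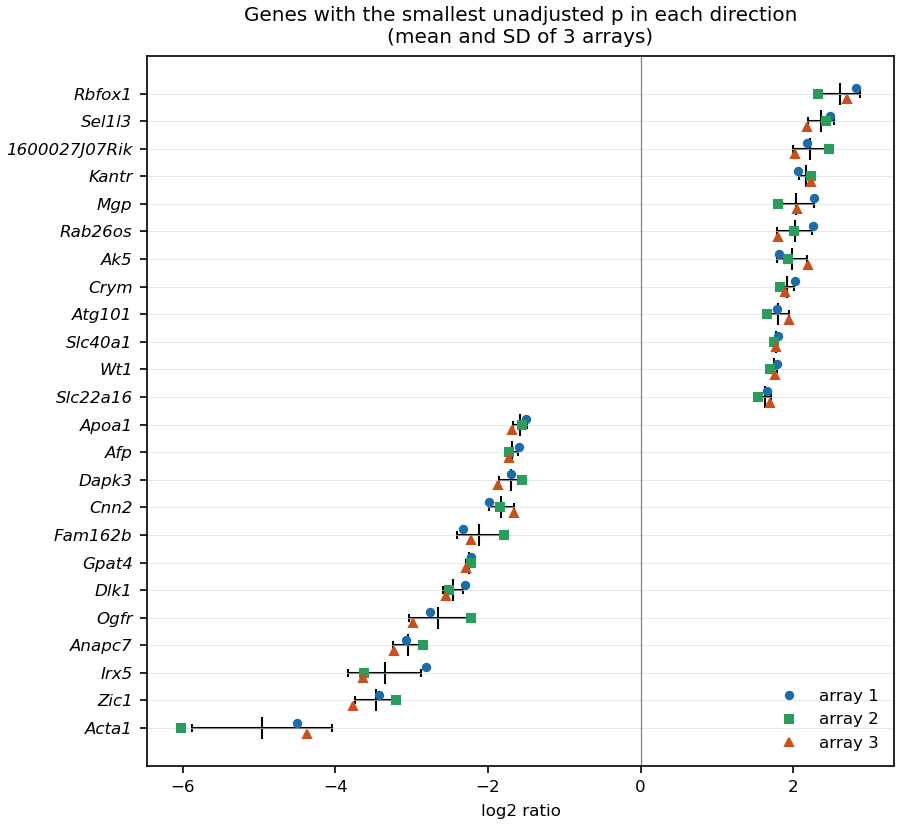
Log2 ratios of the 24 genes with the smallest unadjusted p among those with the same sign on all 3 arrays, 12 on each side. Genes are on the vertical axis and the log2 ratio is on the horizontal axis. Points are the 3 arrays, the vertical tick is their mean and the bar is their SD. Acta1 lies lowest at a mean of -4.96, and Rbfox1 highest at 2.62.

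Kidney development genes chosen beforehand spread from Cd24a at 1.87 ± 0.91 to Ret, the receptor of the ureteric bud, at -0.43 ± 0.11. Besides Wt1 and Foxd1, the positive side held Wnt4, which drives the mesenchyme to form epithelium, at 1.03 ± 0.06, Cited1 at 0.86 ± 0.29, Cdh11 at 0.66 ± 0.32 and Gata3 at 0.64 ± 0.53. The ligand gene Gdnf had 0.32 ± 0.10 and Wnt9b had 0.24 ± 0.04. Wnt11 had 0.20 ± 0.23. Six2 had 0.27 ± 0.35, Eya1 had 0.14 ± 0.76, Bmp7 had 0.10 ± 0.51, Sall1 had 0.09 ± 0.27, Hoxd11 had -0.08 ± 0.12 and Pax2 had -0.33 ± 1.16, and each of these had arrays on both sides of 0. Osr1 at -0.36 ± 0.08 and Hoxa11 at -0.36 ± 0.10 were negative on every array. With array 3 turned the other way, Cdh11 had -0.0234, Gata3 had -0.18, Wnt11 had -0.11 and Pax2 had 0.74. None of the 19 measured genes passed adjustment over all genes by limma. Lhx1 had a value on array 1 alone, at -2.05, and was not tested.

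**Figure D2:**
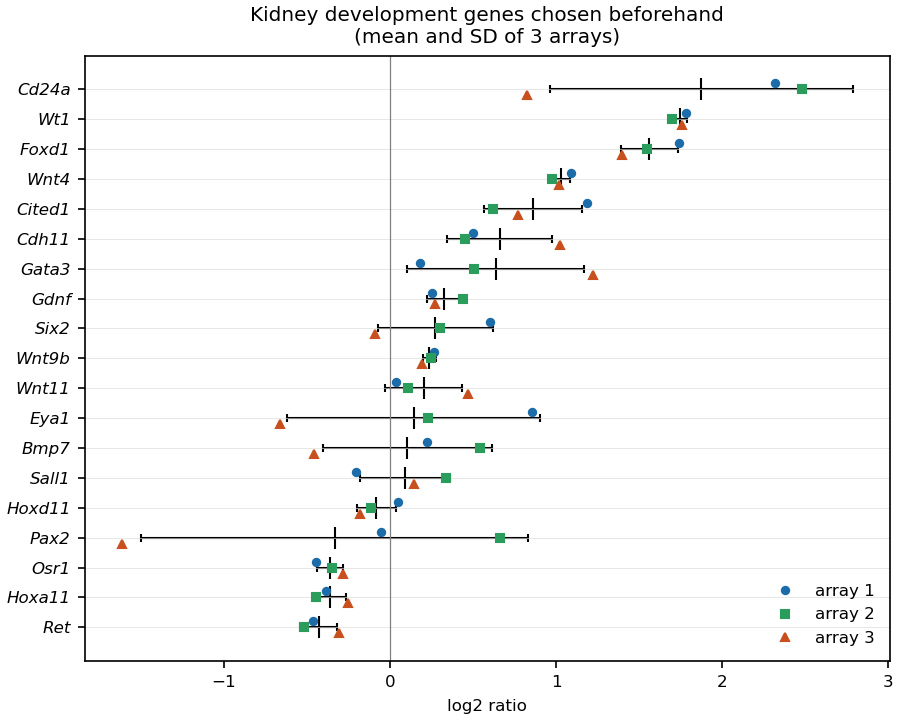
Log2 ratios of 19 kidney development genes chosen beforehand, with genes on the vertical axis and the log2 ratio on the horizontal axis. Points are the 3 arrays, the vertical tick is their mean and the bar is their SD. Wt1 and Wnt4 have SDs of 0.04 and 0.06, and Pax2 has an SD of 1.16.

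In the list of metanephric mesenchyme and nephron progenitor genes, 2 of 29 measured members passed when adjusted over the list alone, Crym and Wt1, both positive, and 0 passed over all genes. Rspo1 had 1.08 ± 0.43. The list's median was 0.14 and its camera adjusted p was 0.0991. Of 22 measured renal stroma genes, 7 passed adjusted over the list alone, 6 of them positive. These included Foxd1, Tcf21 at 1.47 ± 0.17, Meis1 at 1.00 ± 0.07, Meis2 at 1.19 ± 0.29 and Hic1 at 2.07 ± 0.60, while Dlk1 was the negative member. The stroma list had a median of 0.22 and a camera adjusted p of 0.0991.

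Ureteric bud genes lay on both sides. Adjusted over the list alone, 3 of 39 passed, the calcium binding protein gene Calb1 at 1.16 ± 0.10 and Mia at 2.32 ± 0.58 on the positive side and the tight junction gene Cldn6 at -1.01 ± 0.14 on the negative side. Etv4 had 0.81 ± 0.18. The median was 0.09 and the camera adjusted p was 0.446, and the list's sign turned without array 3. Among 24 induced mesenchyme and early nephron genes, 3 passed adjusted over the list alone, C1qtnf12 at 1.33 ± 0.23 and Wnt4 on the positive side and Greb1 at -1.11 ± 0.34 on the negative side. Pax8 had -0.66 ± 0.11. That list's median was -0.03 while camera placed it on the positive side, with an adjusted p of 0.964. Of 18 genes of Hox paralog groups 1 to 8, 3 passed adjusted over the list alone, Hoxd4 at 0.91 ± 0.08, Hoxa5 at 1.08 ± 0.24 and Hoxa7 at -0.999 ± 0.339. Its median was 0.21 and its camera adjusted p was 0.195. Of 13 genes of Hox groups 9 to 13, 0 passed adjusted over the list alone, with a median of 0.05 and a camera adjusted p of 0.812. Hoxd10 had 0.79 ± 0.34, Hoxa13 had -1.40 ± 0.84 and Hoxc12 had 0.85 ± 0.81.

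Of 10 limb bud genes, 5 passed adjusted over the list alone and all 5 were negative. They were Pitx1 at -1.95 ± 0.35, Msx1 at -1.44 ± 0.43, Prrx1 at -1.14 ± 0.38, Prrx2 at -0.75 ± 0.24 and Msx2 at -0.72 ± 0.23, which encode homeodomain transcription factors. The list's median was -0.67, and by camera its adjusted p was 0.0110. Of 18 somite and muscle genes, 7 passed adjusted over the list alone, 6 negative and 1 positive. The negative members included Acta1, the contractile protein genes Myl1 at -2.66 ± 0.89 and Tnnc1 at -2.72 ± 1.04, and the somite transcription factor gene Tcf15 at -1.78 ± 0.49, and the positive member was Meox2 at 0.62 ± 0.11. The cardiac actin gene Actc1 had 0.43 ± 0.55. The list's median was -0.42 and its camera adjusted p was 0.0480. With an estimated correlation both lists missed the threshold, at an adjusted p of 0.616. The estimated correlations were -0.041 for limb bud and 0.009 for somite and muscle. Both lay under the preset 0.01, so correlated members do not account for these losses. The limb bud call ended without array 3, at an adjusted p of 0.0687, and the somite and muscle call ended without array 3, at 0.0687, and without array 1, at 0.0523.

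Gut and liver genes lay on both sides, with 7 positive and 8 negative means. Of 15 measured, 4 passed adjusted over the list alone, all negative: Afp, Apoa1, the transthyretin gene Ttr at -1.13 ± 0.15 and the transferrin gene Trf at -1.34 ± 0.49. The albumin gene Alb had 0.36 ± 0.23. The list's median was -0.12 and its camera adjusted p was 0.262. Endothelial genes had a median of -0.18 and a camera adjusted p of 0.0480, with 0 of 19 members past the threshold adjusted over the list alone and an adjusted p of 0.616 with an estimated correlation. Cldn5 had -1.12 ± 0.31, Sox17 had -1.02 ± 0.31, Pecam1 had -0.59 ± 0.13 and Plvap had -0.43 ± 0.03. That call ended without array 1, at an adjusted p of 0.194, and without array 3, at 0.107.

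Among 17 erythroid genes, 1 passed adjusted over the list alone, the transcription factor gene Klf1 at -1.10 ± 0.14, and the globin genes Hbb-y at 0.01 ± 0.26 and Hba-x at -0.02 ± 0.28 lay near 0. The list's median was -0.03 and its camera adjusted p was 0.656. Macrophage and leukocyte genes had a median of 0.15 and a camera adjusted p of 0.195, with 0 of 15 past the threshold adjusted over the list alone. Tyrobp had 0.70 ± 0.17 and Lyz2 had 0.81 ± 0.27. Of 16 neuron and neural crest genes, 1 passed adjusted over the list alone, Dcx at 1.40 ± 0.29, and Tubb3 had -0.60 ± 0.04. The median was -0.09 and the camera adjusted p was 0.557. Gonad and germ cell genes had a median of -0.17 and a camera adjusted p of 0.497, with 0 of 13 passing adjusted over the list alone.

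Oxidative phosphorylation was the called list on the positive side. Its 71 measured members had a median of 0.19 and a camera adjusted p of 0.0480, and 1 of them, Uqcrb at 1.66 ± 0.13, passed adjusted over the list alone. Of the members, 55 had a positive mean and 16 a negative mean. Ndufa4 had 1.16 ± 0.21, and Sdhc had -0.92 ± 0.13. Imprinted growth genes were called on the negative side, with a median of -0.23 and a camera adjusted p of 0.0480. Of their 15 members 1 passed adjusted over the list alone, Dlk1. H19 had -1.17 ± 0.43, Ndn had -0.62 ± 0.12 and Snrpn had -0.51 ± 0.08, although its 2 probes had means of -1.11 and 0.08. Both lists had an adjusted p of 0.616 with an estimated correlation. Leaving out any 1 array ended both calls, with an adjusted p of 0.0523 without array 1 and 0.103 without array 2 for both, and without array 3 of 0.107 for oxidative phosphorylation and 0.0687 for imprinted genes. Array 3 turned the other way ended all 5 list calls, each at an adjusted p of 0.502, and median centring ended all but that of limb bud, at 0.0578, while a dye term did the same with adjusted p from 0.0671 to 0.123. With the dye term the list means went from -0.27 to -0.28 for endothelium, from 0.15 to 0.14 for oxidative phosphorylation and from -0.411 to -0.408 for imprinted genes, and the somite and muscle mean was -0.79 in both fits.

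**Figure D3:**
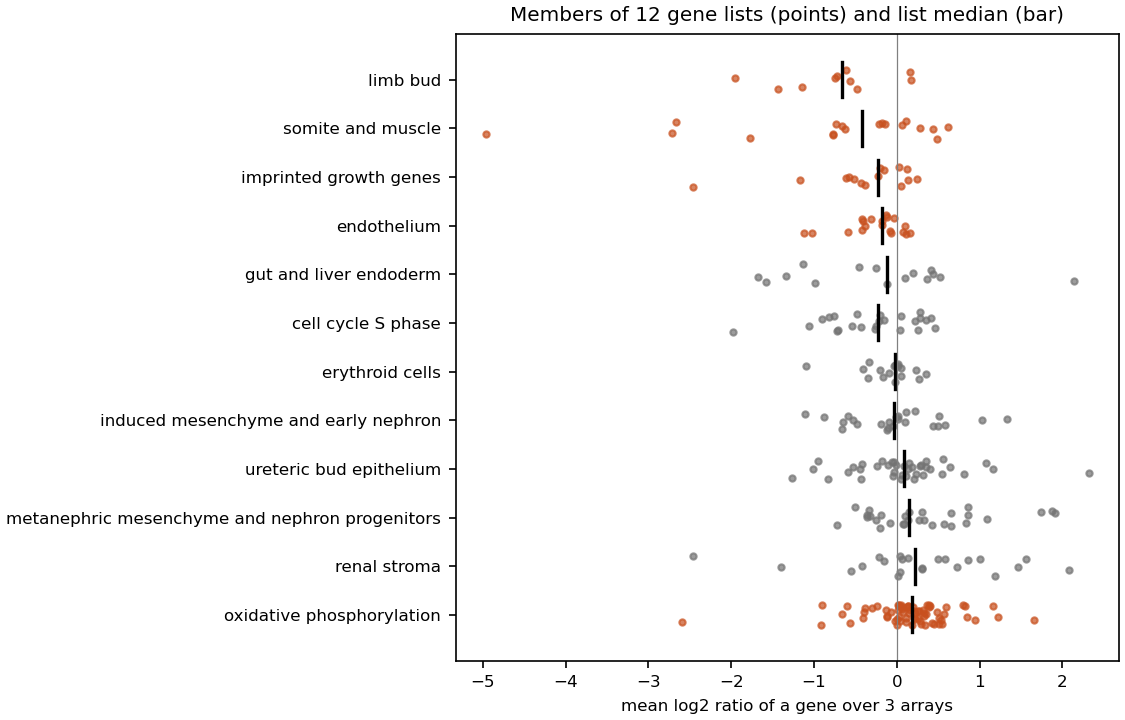
Mean log2 ratios over 3 arrays of the members of 12 gene lists, with lists on the vertical axis and the log2 ratio on the horizontal axis. Each point is a gene, the black bar is the list's median, and orange marks the 5 lists with a camera adjusted p under 0.05. The limb bud list has the lowest median, at -0.67, and the renal stroma list a median of 0.22.

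Cell cycle S phase genes had a median of -0.23 and a camera adjusted p of 0.0991, with 0 of 24 past the threshold adjusted over the list alone. Rrm2 had -1.06 ± 0.31 and Fen1 had -0.82 ± 0.09. The list of G2/M genes had a median of -0.03 and an adjusted p of 0.557. Immediate early and heat shock genes had a median of -0.23 and an adjusted p of 0.195, and 2 of 13 passed adjusted over the list alone, Ier2 at -1.67 ± 0.24 and Junb at -1.02 ± 0.27. Glycolysis and hypoxia genes had a median of 0.06 but a mean of -0.14 and a camera direction on the negative side, at an adjusted p of 0.628. Slc2a1, a glucose transporter gene, had -1.18 ± 0.45. Cytosolic ribosomal protein genes had a median of 0.07 and an adjusted p of 0.195. They were called on the positive side with a dye term, at an adjusted p of 0.0276, and without array 2, at 0.0438, and on the negative side with array 3 turned the other way, at 0.0235. With an estimated correlation, which was 0.344 for this list against the preset 0.01, the adjusted p was 0.861. With the dye term the estimated correlation was 0.007 and the adjusted p was 0.794. That correlation lay under the preset 0.01, so correlated members do not account for the call lost with the dye term. Basement membrane and extracellular matrix genes had a median of -0.04, a mean of 0.03 and a camera direction on the negative side, at an adjusted p of 0.905.

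Of the signalling lists, FGF and ERK targets had a median of 0.16 and a camera adjusted p of 0.446, and 2 of 11 members passed adjusted over the list alone, Spry2 at 1.09 ± 0.06 and Etv4. BMP targets had a median of 0.07 and an adjusted p of 0.648, with 2 of 12 passing adjusted over the list alone, Bmper at 1.84 ± 0.21 and Msx1. Wnt targets had a median of -0.29 and an adjusted p of 0.246, hedgehog targets had -0.25 and 0.365, Notch targets had -0.13 and 0.802, and the retinoic acid pathway had 0.14 and 0.365. Housekeeping genes had a median of -0.08 and an adjusted p of 0.905. None of the members of these 5 lists passed adjusted over the list alone. Sex chromosome markers, too few for the list test with 4 measured, held Xist at 1.56 ± 0.17, which passed adjusted over the list alone, Kdm5d at -0.79 ± 0.55, Uty at 0.62 ± 0.48 and Eif2s3y at 0.04 ± 0.42.

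At probe level 0 of 19660 probes passed an adjusted p of 0.05 by limma, and the smallest adjusted p was 0.193. At an unadjusted p under 0.05 there were 3432 probes, 1782 positive and 1650 negative, where 983 would be expected by chance. There were 2750 genes, 1389 positive and 1361 negative, where 702 would be expected. The expected counts take no account of a dye effect shared by arrays 1 and 2. With a dye term in the fit the counts were 3645 probes and 2994 genes. Without variance moderation 0 probes and 0 genes passed the adjusted threshold. The probe count at an unadjusted p was 1377 without array 1, 1606 without array 2 and 3690 without array 3. The gene count was 1156 without array 1, 1453 without array 2 and 2943 without array 3. Leaving out array 3 keeps the arrays of the same dye order.

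Ratios agreed best between arrays 1 and 2, which had the same dye order. Across 19660 probes, which are not independent replicates, the Spearman correlation was 0.466 between arrays 1 and 2, 0.211 between arrays 1 and 3 and 0.171 between arrays 2 and 3. The Pearson correlations were 0.324, 0.0517 and 0.0148. Without the 1% of probes with the largest mean ratio in size, the Pearson correlation of arrays 2 and 3 was -0.0268. A large mean over the 3 arrays favours probes on which the arrays agree, so a fall is partly built in. The same sign on all 3 arrays was found for 8593 probes, which is 43.7%. Arrays 1 and 2 had the same sign for 13843 probes, and array 3 shared it in 62.1% of these. Where every array had at least 0.5 in log2 size, array 3 shared it in 69.9% of 2450. Of the 503 probes with a log2 ratio of at least 1 in size on every array and the same sign on arrays 1 and 2, array 3 had that sign in 64.8%, and of the 54 with at least 2 in size, in 40.7%. The array medians were 0.05 on arrays 1 and 2 and -0.05 on array 3.

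**Figure D4:**
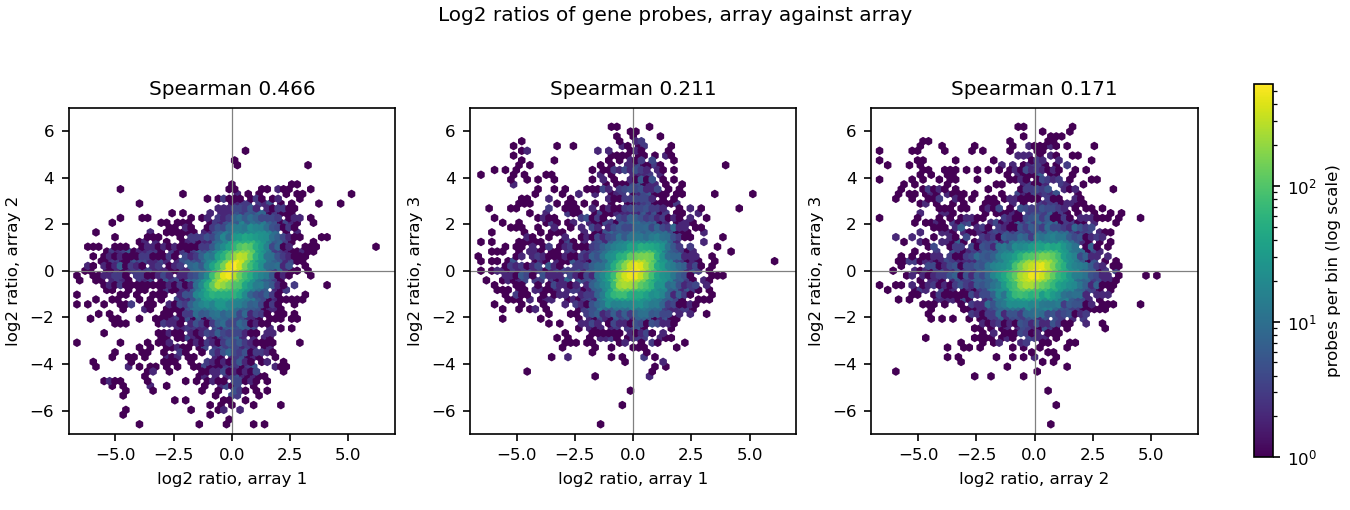
Log2 ratios of 19660 gene probes on one array against another, with the log2 ratio of an array on each axis and colour giving the number of probes per bin on a log scale. The Spearman correlation is 0.466 for arrays 1 and 2, 0.211 for arrays 1 and 3 and 0.171 for arrays 2 and 3.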

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

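The counts at an unadjusted p and by limma's B statistic were chosen after seeing the data. At an adjusted p of 0.05 the count stayed at 0 probes and 0 genes under every alternative run. That shows little about stability, since true differences can also give 0 calls, as log2 ratios of 1 and 2 did in the simulation. The simulation held the number of changed features fixed, and a larger share was not simulated. Its calls therefore do not measure the power in these data. The B statistic above 0 gave 92 probes and 96 genes, against 5 and 16 with array 3 turned the other way and 0 of either with array 1 or array 2 turned. At an unadjusted p the probe count was 1158 with array 3 turned the other way and 1377 to 3690 with an array left out, and the gene count was 779 and 1156 to 2943. Array weights gave higher counts, 4929 probes and 3827 genes. The number of lists called was 1 after median centring, 2 with the dye term (limb bud and, newly, ribosomal proteins on the positive side at an adjusted p of 0.0276), 1 with array 3 turned, 0 with an estimated correlation and 0 to 4 with an array left out. By fry, which does not compare a list with other genes, it was 6, of which 3 were positive and newly called, renal stroma, Hox groups 1 to 8 and FGF and ERK targets, each at an adjusted p of 0.0333. Limb bud stayed called under 7 of 10 alternatives, somite and muscle under 4, endothelium and imprinted growth genes under 3 and oxidative phosphorylation under 2, on the same side throughout, with adjusted p from 0.00598 to 0.616 for limb bud. With an array left out fewer samples enter the test. Among those fits the highest counts at an unadjusted p, 3690 probes and 2943 genes, came without array 3. Otherwise the cause was not tested. The correlations of arrays 1 and 2, 1 and 3, and 2 and 3 were 0.466, 0.211 and 0.171 by Spearman. By Pearson they were 0.324, 0.0517 and 0.0148, and 0.287, 0.0164 and -0.0268 without the largest 1%. What signal over background limits could not be read from ratios.

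Some lists that were not called changed sides. With array 3 turned these were, with their adjusted p, ureteric bud at 0.382, early nephron at 0.832, renal stroma at 0.989, Hox groups 1 to 8 at 0.966, G2/M at 0.832, FGF and ERK targets at 0.966 and ribosomal proteins, which then passed, at 0.0235. With the dye term they were early nephron at 0.865, basement membrane at 0.841 and housekeeping at 0.886, with values on at least 2 arrays basement membrane at 0.964, and by fry housekeeping at 0.917. With an array left out the adjusted p ran from 0.194 to 0.868 for ureteric bud, 0.835 to 0.964 for early nephron, 0.604 to 0.928 for Hox groups 9 to 13, 0.499 to 0.964 for erythroid genes and for Notch targets, 0.653 to 0.964 for basement membrane, 0.0438 to 0.499 for ribosomal proteins and 0.561 to 0.928 for housekeeping.

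Of 148 named genes, 21 changed sign under at least 1 alternative. The signs of the others show little, since most were chosen for like values on the 3 arrays, and sizes did change, as for Wt1 from 1.75 to 0.58 with array 3 turned. With array 3 turned the log2 ratio was -0.32 for Hoxc12, -0.0763 for Adgre1, 0.0201 for Neurog2, 0.69 for Prdm1, -0.10 for Frem2, -0.0122 for Lamb1, -0.0237 for Col6a1, 0.13 for Notum, 0.0256 for Aldh1a2, 0.0176 for Pgk1, 0.0122 for Pfkl, 0.0703 for Pgam1, -0.30 for Eif2s3y, 0.74 for Pax2, -0.0032 for Sall1, -0.11 for Wnt11, 0.0379 for Hoxd11, -0.0234 for Cdh11 and -0.18 for Gata3. Array weights gave -0.0572 for Eif2s3y and -0.025 for Sall1, and the dye term -0.0587 for Eya1 and -0.0354 for Bmp7. With an array left out the log2 ratio ran from -0.11 to 0.38 for Bmp7, -0.20 to 0.21 for Eif2s3y, -0.22 to 0.54 for Eya1, -0.83 to 0.31 for Pax2 and -0.0299 to 0.24 for Sall1.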

Other observations

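The gene families, the regulators, the exchange of tissues on single arrays, the look at the largest ratios and the count of list members were chosen after the data were seen. The list tests, with a dye term, array 3 turned or an estimated correlation, were fixed beforehand, but their use to weigh explanations was not. Among 207 families of at least 8 genes sharing a symbol root, 1 had a camera adjusted p under 0.05, the Snhg genes, which host small nucleolar RNAs. All 10 had a positive mean, with a median log2 ratio of 0.55 and an adjusted p of 0.0348. Snhg5 had 1.19 ± 0.27 (SD, n = 3), Snhg20 had 0.67 ± 0.18 and Snhg8 had 0.55 ± 0.20, while Snhg10 had 1.84 ± 1.84 and Snhg16 had 0.03 ± 2.33, with array 2 at -2.50. By camera the adjusted p was 0.0149 without array 2 and 0.0151 with a dye term. It was 0.187 without array 1, 0.175 without array 3, 0.774 with array 3 turned the other way and 0.999 with an estimated correlation.

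Among transcription factor genes outside the fixed lists, Foxc1 had 0.90 ± 0.04, Foxc2 had 0.94 ± 0.08 and Pbx3 had 0.74 ± 0.38. On the other side Tbx15 had -0.93 ± 0.42, Irx1 had -0.49 ± 0.13 and Foxa3 had -0.79 ± 0.25. They were picked after their values were seen, each with an unadjusted p under 0.05 by limma. Over all genes 19.6% had such a p. Each had the same sign on all 3 arrays, which that choice partly builds in, and none passed adjustment over all genes. Other such genes lay near 0, as Foxp2 at 0.02 ± 0.07 and Irx3 at -0.16 ± 0.02. The 8 Gapdh control spots with values on all arrays ranged on array 1 from -0.95 to 0.52. The dye coefficient had a camera adjusted p of 1.08e-05 for cytosolic ribosomal proteins and 0.0428 for ureteric bud genes, both on the negative side, at the preset correlation of 0.01. Both missed the threshold at an adjusted p of 0.903 with an estimated correlation, a test that was added after the data were seen. The estimated correlations were 0.007 for ribosomal proteins and -0.026 for ureteric bud genes, both under the preset 0.01. That test rests on few degrees of freedom, so these losses do not speak against a dye effect.

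Exchanging the tissues on 1 array at a time gives 4 assignments, too few for a share under 0.05. The deposited orientation was 1 of the 4 with as many results, with 3432 probes at an unadjusted p under 0.05 against at most 1158 in the others, 2750 genes against at most 779, and 5 lists called against at most 1.

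The largest ratios of array 3 lay on the other side from those of arrays 1 and 2. Of ratios beyond 3 in log2 size, 92.9% were negative on array 1, 90.4% on array 2 and 21.2% on array 3. Among probes of at least 2 in log2 size on every array, the 12 positive on arrays 1 and 2 were all positive on array 3. Of those negative on arrays 1 and 2, 10 were negative on array 3 and 32 positive. The 104 probes under -2 on arrays 1 and 2 had a median of 0.83 on array 3. That median restates the pattern and decides nothing between a dye effect in a table already turned to one orientation and a table in which array 3 was not turned, either of which may give it. Of 12 cell type lists 3 were called as deposited and 0 with array 3 turned. With an estimated correlation 0 were called as deposited, but that test rests on few degrees of freedom and decides nothing here. The contrast of 3 against 0 does not decide either. Had array 3 not been turned, a dye effect could give calls as deposited. Neither explanation is excluded, and a difference between the tissues stays open as well.

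Limb bud, somite and muscle markers lay on the negative side, with 11 of 28 members negative and 1 positive at an unadjusted p under 0.05 by limma. With a dye term 14 were negative and 1 positive. Of the members, 3 also stand in other lists. The limb bud list kept a camera adjusted p of 0.0276 with a dye term, and its mean went from -0.73 to -0.75. That term parts dye from tissue only if array 3 was already turned, and array 3 alone had the other dye order. A dye effect therefore stays open. The adjusted p was 0.502 with array 3 turned and 0.616 with an estimated correlation, or 0.794 with that and the dye term. Calls lost at an estimated correlation, with few degrees of freedom, do not speak for a dye effect. The somite and muscle list had a mean of -0.79 with a member SD of 1.43 both before and after the dye term. Its call ended at an adjusted p of 0.102, where the dye term leaves fewer degrees of freedom. That lost call does not speak for a dye effect. As for limb bud, the orientation of array 3 leaves a dye effect open. More surrounding tissue in one of the dissections may account for the pattern, and cannot be told apart from a difference in age, since the 2 dissections are also the 2 ages. Acta1 at -4.96 goes with it, while Actc1 at 0.43 does not.

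One hypothesis is that positive ratios stand for more RNA at 11.5 dpc, when the ureteric bud has entered the mesenchyme. The ureteric bud list had a median of 0.09 and a camera p of 0.277, which leaves the direction open, and Calb1 at 1.16 and Ret at -0.43 lay on opposite sides.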
